A study of Rattus norvegicus with 6 samples.

How the data were processed

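The measurements were gene expression values of cultured rat hepatic stellate cells, the vitamin A-storing cells of the liver that turn into matrix-producing myofibroblasts in fibrosis. Total RNA from 6 samples was amplified, labelled with biotin and hybridised to an Affymetrix rat whole-genome array with a 3'-biased labelling kit, per the labels' protocols. Samples were grouped by the infection named in their labels: 3 arrays of cells infected with pLV-miR-16, a construct named for the microRNA miR-16, and 3 arrays of cells infected with pLV-GFP, named for green fluorescent protein. The labels number the arrays 1 to 3 in each group and do not say whether a number stands for a culture, an animal or a hybridisation, so p-values measure only the spread between these samples, which may be technical. The labels also disagree on the cells, calling them quiescent in the source name and activated in the description. Untransduced quiescent and activated cells, which the series' design text lists as further groups, were not analysed here.

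The deposited values are log2 signals, 1 per probe set and array. Per the submitters' processing notes the signals were made with MAS5, Affymetrix's algorithm that summarises the probes of each array on its own and scales the array to a common target; its version and settings are not given in the sources used here. The deposited log2 values bore out a scaling per array: turned back to the linear scale, their mean with 2% trimmed from each end was 500.2 on every array. They end at 0 on the log2 scale, and between 0.15% and 1.64% of the probe sets of an array lay at that floor. The values carry no detection calls, so whether a probe set was above background could not be judged by call. MAS5 subtracts a mismatch-based background, which makes differences of dim probe sets unstable and large folds against a dim level uncertain. Array number, not read depth, limits the precision here.

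The table held 31099 probe sets, of which 57 were Affymetrix controls and were left out of the tested probe sets, leaving 31042. A platform table gave 20832 probe sets 1 gene and 436 several, and 9780 of the non-control probe sets were not listed in it and stay unnamed here. Gene symbols were updated through the Entrez identifier to the RefSeq annotation of assembly GRCr8, which matched 20764 of the single-gene probe sets; that annotation served for names and for which genes neighbour each other only, and no coordinates are given because the files name no genome build. Genes with several probe sets were represented by the probe set with the highest mean over the 6 arrays, which gave 14217 genes. Probe sets were tested where their mean log2 signal over all 6 arrays was at or above the 40th percentile, a level of 5.27, which kept 18625 probe sets and 10165 genes.

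Each kept probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on the deposited log2 values, without further scaling and without a pseudocount, since the values already were logarithms. The difference was taken as pLV-miR-16 minus pLV-GFP, so a log2 difference above 0 is a higher signal after pLV-miR-16 infection. Standard errors are limma's moderated ones. P-values were adjusted by Benjamini-Hochberg over all probe sets tested, with a threshold of 0.05, and a second count required a difference of at least 1 on the log2 scale as well. With 3 arrays against 3, an exact permutation test of a single gene cannot go below a two-sided p of 0.1.

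Gene groups came from 29 lists fixed before the data were examined, covering matrix, contractile and stellate cell genes, reported miR-15/16 targets, cell cycle, stress, inflammatory, signalling and metabolic genes, and markers of other liver cell types; 22 older symbols in them were updated. The 26 lists with at least 5 measured genes were tested with limma's camera on 1 probe set per gene at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, beside camera with a correlation estimated per list and fry. Camera asks whether a list shifted relative to the other genes, whereas fry asks whether its genes moved, on balance, in a single direction. For each list, counts adjusted over the list alone are given beside those adjusted over all probe sets tested. A planned test of genes with a miR-16 seed match in their 3' untranslated region was not run, because untranslated region sequences were not used here.

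The genes named were set by a rule fixed before the data were examined: the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, from each list up to 2 risen and 2 fallen members with the smallest p or, where none passed, the member with the smallest p given as values, and always Ccnd1, Ccne1, Cdk6, Bcl2, Gna12, Wee1, Chek1, Acta2, Col1a1, Timp1, Pparg, Dleu2 and Smc4. Genes named outside it are said to be so.

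Whether the shared array numbers pair the samples was checked before the blocked calls were compared. The deviations of same-numbered arrays from their group means correlated across probe sets at 0.20 for number 1, 0.11 for number 2 and 0.12 for number 3, all above 0.1, so the numbers were treated as pairs. The pairing rests on the data alone, as the labels do not state it, and the main fit does not use it. Deviations cancel out within a group and arrays 2 and 3 lay close together, so the 3 values are not independent. They show at most something shared by the arrays numbered 1. Arrays 2 and 3 were not told apart by it, since pLV-GFP array 3 with pLV-miR-16 array 2 gave 0.22 and pLV-GFP array 2 with pLV-miR-16 array 3 gave 0.13.

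The counts, the named genes and the tested lists were recomputed with pseudocounts of 16 and 64 on the linear scale, quantile normalisation, equal array medians, no filter and a filter at the 60th percentile, eBayes without the trend and with robust estimation, array weights, 1 probe set per gene (counts of probe sets only), the mean over all probe sets of a gene (lists only), the replicate number as a block, and each array left out. Alternatives added after seeing the data were the arrays numbered 1 as a batch, both arrays numbered 1 left out, arrays 2 and 3 of each group averaged into 1 replicate, and the 5' to 3' signal difference of beta-actin as a covariate. Levels, percentiles and array correlations were computed once.

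The fit was tested on simulated data before use: with the residual spread of the real arrays over 18625 probe sets and 200 changed ones, it called 0% of probe sets changed 1.5-fold, 4% of those changed 2-fold, 56% of those changed 4-fold and 82% of those changed 8-fold in this comparison. With no probe set changed it called 0. The simulated values were drawn independently, with the same spread on every array. These figures therefore do not cover genes that move together, arrays that resemble each other or an array that stands apart. Figures were drawn with matplotlib 3.10.9.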

Results

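Gene expression was measured in rat hepatic stellate cells infected with pLV-miR-16 and in cells infected with pLV-GFP, with 3 arrays in each group. The comparison asks which transcripts differed between cells given the miR-16 construct and cells given the GFP construct. The level of mature miR-16 was not analysed here. Dleu2, the host transcript of miR-16, had no matched probe set, and Smc4, whose intron holds a second copy, had a log2 difference of 0.25 ± 0.58 (SE, n = 3 per group, adjusted p = 0.899).

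The 6 arrays did not form 2 compact groups. Arrays 2 and 3 of each group were close to each other, with a Pearson r across the tested probe sets of 0.987 for pLV-GFP and 0.985 for pLV-miR-16, and held 0 identical values. The labels do not say whether arrays 2 and 3 of a group are repeats of the same culture. Array 1 of pLV-GFP correlated with arrays 2 and 3 of its group at 0.945 and 0.942. Array 1 of pLV-miR-16 correlated with the other 5 arrays at 0.855 to 0.874, no better with its own group (mean 0.859) than with pLV-GFP (mean 0.865). Genes are not independent replicates, so these correlations describe the arrays only. The first principal component held 50.2% of the variance and set pLV-miR-16 array 1 apart from the rest. The 5' minus 3' log2 signal of beta-actin, a measure of RNA integrity, was -1.67, -2.88 and -3.18 on the pLV-GFP arrays. It was -3.16, -3.88 and -3.56 on the pLV-miR-16 arrays. That of GAPDH was -0.26, -0.2 and -0.18 on the pLV-GFP arrays and -0.21, -0.38 and -0.21 on the pLV-miR-16 arrays. The beta-actin difference was mostly lower in pLV-miR-16, so using it as a covariate can also take away a difference between the groups.

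**Figure D1:**
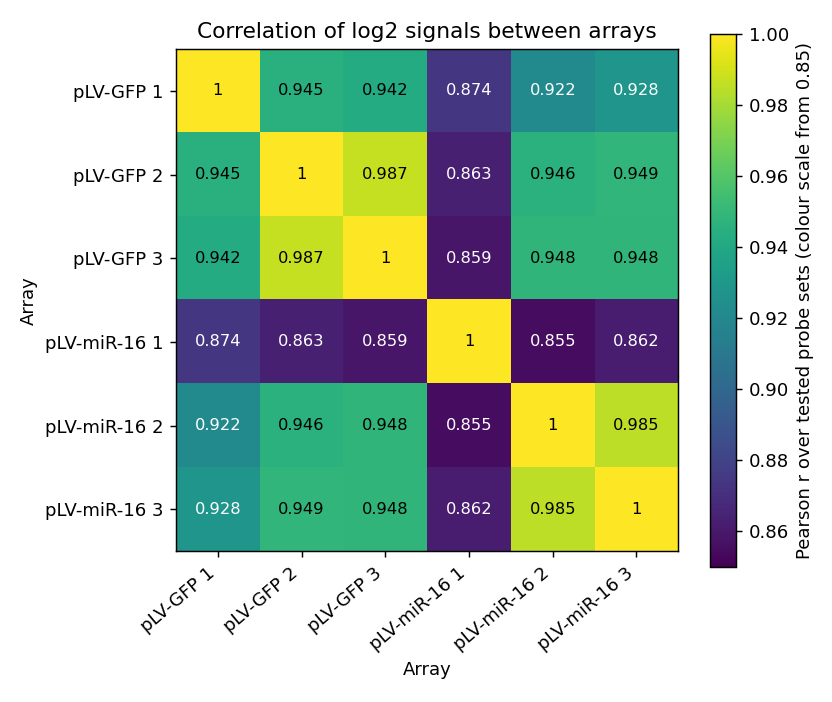
Pearson r between the log2 signals of each pair of the 6 arrays over the tested probe sets, with a colour scale that starts at 0.85. Arrays 2 and 3 of a group reach 0.987 and 0.985, while pLV-miR-16 array 1 lies between 0.855 and 0.874 with every other array.

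In the fit without a replicate block 32 genes were called higher and 30 lower after pLV-miR-16 infection. Among them were Serpinb2, Cxcl2 and Cxcl11 on the higher side and Tspan8 and Col3a1 on the lower. With the replicate number as a block 53 of these 62 genes lost their call, in a fit that estimates more terms from the same arrays and so has less power. With arrays 2 and 3 of each group averaged, 0 probe sets passed. Serpinb2, a plasminogen activator inhibitor induced in inflammation, was 44.9-fold higher (log2 difference 5.49 ± 0.61, adjusted p = 0.0199), from a mean log2 signal of 7.86 ± 0.90 (SD, n = 3) to 13.35 ± 1.04. The neutrophil-attracting chemokine Cxcl2 was 30.1-fold higher (4.91 ± 0.55, adjusted p = 0.0199) and the T cell-attracting chemokine Cxcl11 16.6-fold higher (4.06 ± 0.35, adjusted p = 0.0107). On the other side, Tspan8, a tetraspanin of epithelial cells, was 29.1-fold lower (-4.86 ± 0.63, adjusted p = 0.0326; 0.0545 with the replicate number as a block), and Col3a1, the type III collagen chain, was 14.8-fold lower (-3.89 ± 0.37, adjusted p = 0.0128), from 12.85 ± 0.39 to 8.96 ± 0.68.

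In all, 92 of 18625 probe sets passed the threshold in limma's test, 47 higher and 45 lower, and 90 of them differed at least 2-fold. They included the representative probe sets of 62 genes, 32 higher and 30 lower. All 92 had groups that did not overlap, which held for 21% of the tested probe sets. The share by chance would be 10% if all arrays were equally alike. Arrays 2 and 3 of each group lay close together, so the 10% is no fitting baseline and the 21% shows no excess by itself. An unadjusted p under 0.05 was found for 2146 probe sets (11.5%). The count of 92 rested on single arrays. It was 0 without pLV-GFP array 2, without pLV-GFP array 3 or without pLV-miR-16 array 3, where 1171, 1178 and 1629 probe sets had an unadjusted p under 0.05, so that in those fits no member of a gene list passed either. It was 4 without pLV-miR-16 array 2, where 1 list member passed, and 1358 without pLV-miR-16 array 1. The 1358 included all 92, in the same direction. With the replicate number as a block 15 probe sets passed, 12 of them shared with the 92, and 2356 had an unadjusted p under 0.05. The block leaves less information on the spread, so its lost calls do not tell weaker differences from lower power. With arrays 2 and 3 of each group averaged into 1 replicate, an alternative added after seeing the data, 0 passed and 655 had an unadjusted p under 0.05. With the beta-actin difference as a covariate, also added after seeing the data, 26 passed, 14 of them shared, and 3163 had an unadjusted p under 0.05. Setting the array medians equal gave 59, 20 higher and 39 lower, so that 33.9% rather than 51.1% of the calls were higher. That scaling moved the median log2 difference by -0.12, from 0.02 to -0.10. The array median was 6.74 on pLV-miR-16 array 1 and 6.31 to 6.39 on the other arrays. The shift therefore came mostly from that array and not from the group as a whole.

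The other large rises were Gdf15, a stress-induced cytokine of the TGF-beta family (4.07 ± 0.49), the stress transcription factor Atf3 (3.18 ± 0.26) and the prostaglandin synthase Ptgs2 (2.98 ± 0.23). Next came the oxidised-lipoprotein receptor Olr1 (2.98 ± 0.41), the chemokine Cxcl3 (2.93 ± 0.32), and the cyclin-dependent kinase inhibitor Cdkn1a (2.76 ± 0.35). They were followed by the chemokine Ccl5 (2.61 ± 0.27), the ubiquitin ligase Neurl3 (2.56 ± 0.16) and the transcription factor Runx1 (2.41 ± 0.29). The other large falls were Tnfaip8l3 (-5.66 ± 0.40), the epithelial polarity gene Crb2 (-4.28 ± 0.37), Fam180a (-3.76 ± 0.33) and the neutral sphingomyelinase Smpd3 (-3.05 ± 0.34). Smaller falls were those of the actin-associated Afap1l2 (-2.71 ± 0.30), the secreted Wnt modulator Sfrp4 (-2.69 ± 0.35), Lrrn4 (-2.46 ± 0.25), the transcription factor Gata6 (-2.37 ± 0.22), the BMP effector Smad9 (-2.35 ± 0.20) and the keratin Krt8 (-2.23 ± 0.31). Adjusted p-values of the 24 genes with the largest changes ran from 0.0104 to 0.0394. Gdf15 and Olr1 lay below the filter level of 5.27 in pLV-GFP, as did Tnfaip8l3, Crb2 and Fam180a in pLV-miR-16, so the sizes of these differences are uncertain. For Runx1, Gata6 and Klf6 only 1 of the kept probe sets passed. With the replicate block, Serpinb2, Cxcl2, Cxcl11, Ptgs2, Ccl5, Neurl3, Tnfaip8l3 and Col3a1 still passed, while the other 16 had adjusted p-values from 0.0528 to 0.137. Of the 24 genes 17 passed with equal array medians, 14 without pLV-GFP array 1, 13 without the eBayes trend, where Serpinb2 and Cxcl2 had an adjusted p of 0.0504 each, 8 with the beta-actin covariate and 3 without pLV-miR-16 array 2. None passed without pLV-GFP array 2, pLV-GFP array 3 or pLV-miR-16 array 3, or with arrays 2 and 3 averaged.

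**Figure D2:**
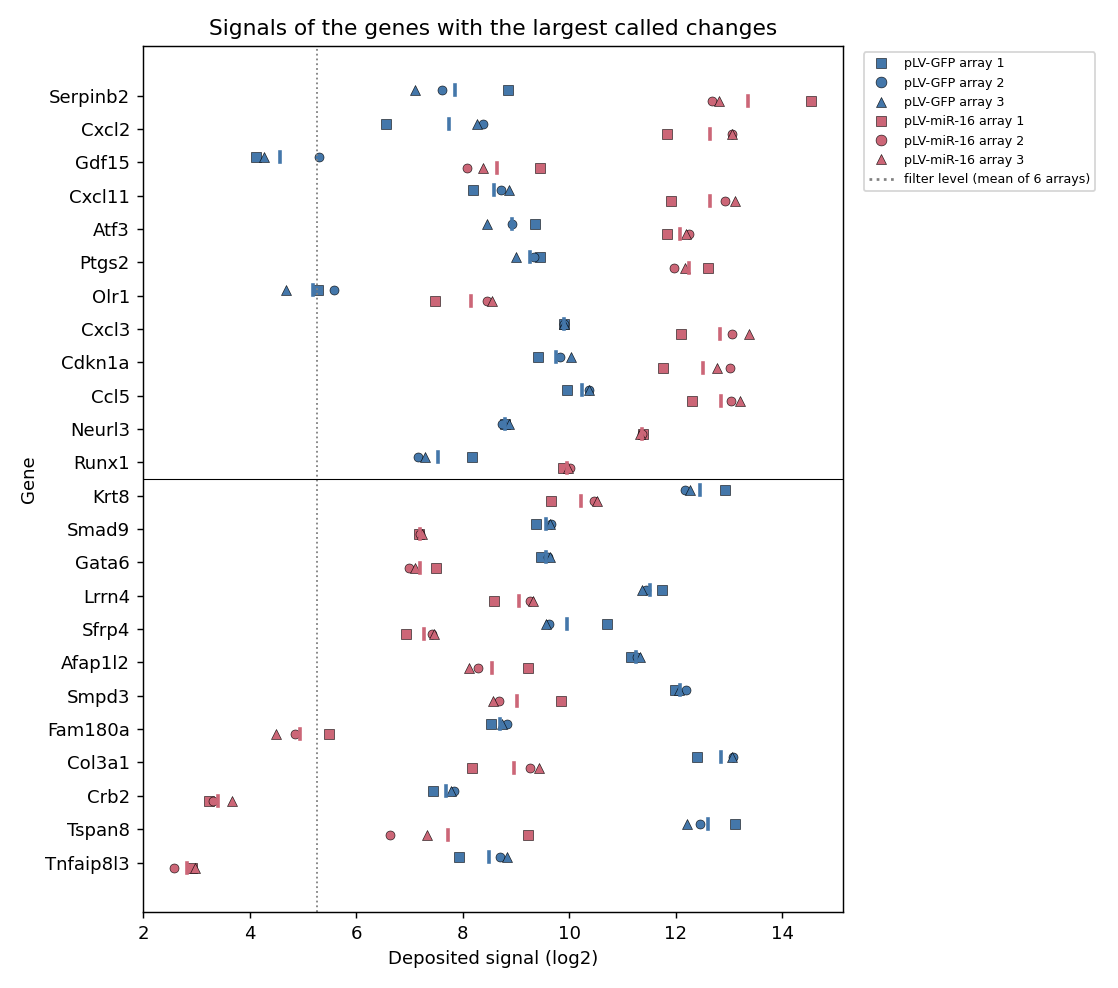
Deposited log2 signals on each array for the 12 genes with the largest called rises (top) and the 12 with the largest called falls (bottom), with vertical bars at the group means and a dotted line at the filter level of 5.27. For each gene the 3 pLV-miR-16 values lie entirely on one side of the 3 pLV-GFP values.

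Inflammatory chemokines and cytokines shifted up. Of 32 measured genes 5 rose and 0 fell, with 27 not passing: Ptgs2, Ccl5, Cxcl2, Cxcl3 and the adhesion molecule Icam1 (1.17, adjusted p = 0.0293), the last named after its values were seen. The mean log2 difference was 1.60 (camera adjusted p = 4.28e-11), and 11 rose when adjusted over the list alone. The call was lost with an estimated correlation, adjusted p = 0.559, and fry gave an adjusted p of 0.0598. With the replicate block 5 rose, of which 3 were the same: Cxcl3 (adjusted p = 0.0607) and Icam1 (0.0909) were lost, and the chemokine genes Ccl7 (0.0113) and Cxcl1 (0.0425), named after their values were seen, were gained. Without pLV-miR-16 array 1, 16 rose, without pLV-GFP array 1, 2, and without pLV-miR-16 array 2, 1. With the beta-actin difference as a covariate the mean was 0.80 (adjusted p = 0.000832). In that fit 2 rose, as did 2 with equal array medians and 2 without the eBayes trend.

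Of 40 measured interferon response genes 3 rose and 0 fell: Cxcl11, Cxcl10 (1.23 ± 0.16, adjusted p = 0.0326) and the antiviral gene Rsad2 (1.74 ± 0.24, adjusted p = 0.0399), the last named after its values were seen. Adjusted over the list alone the count was also 3. With the replicate block only Cxcl11 passed, as Cxcl10 (adjusted p = 0.0757) and Rsad2 (0.118) were lost. In this list 1 rose with equal array medians, 1 without the eBayes trend and 0 with the beta-actin covariate. The mean difference was 0.58 (camera adjusted p = 0.00118; adjusted p = 0.559 with an estimated correlation). This list split the pLV-miR-16 arrays: relative to the mean of all 6 arrays its genes averaged 1.01 on array 2 and 1.01 on array 3 but -1.14 on array 1, against -0.37 to -0.25 in pLV-GFP. Without pLV-miR-16 array 1 the mean was 1.30, with 27 genes risen, and without pLV-miR-16 array 2 or array 3 the call was lost (mean 0.22 in each case, adjusted p = 0.193 and 0.161). It was also lost with arrays 2 and 3 averaged (mean 0.24, adjusted p = 0.146).

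Among p53 targets and cell cycle inhibitors 3 of 25 measured genes rose and 0 fell, namely Cdkn1a, the antiproliferative Btg1 (0.96 ± 0.13, adjusted p = 0.0385) and the stress-induced kinase Plk2 (2.16 ± 0.30, adjusted p = 0.0385), the last named after its values were seen. With the replicate block none of them passed (adjusted p = 0.0528 for Cdkn1a, 0.097 for Btg1 and 0.0757 for Plk2). Adjusted over the list alone 6 rose and 2 fell. The mean difference was 0.59 (camera adjusted p = 0.00808; adjusted p = 0.559 with an estimated correlation). It was the only list that fry called (adjusted p = 0.0381). In this list 10 rose and 2 fell without pLV-miR-16 array 1, and 1 rose without pLV-GFP array 1. With equal array medians 0 rose, without the eBayes trend 0, and with the beta-actin covariate 1. Heat shock and dissociation early genes, the transcripts that respond within minutes to handling or stress, had 2 of 31 risen and 0 fallen, Atf3 and Klf6 (1.72 ± 0.26, adjusted p = 0.0491), with 4 risen over the list alone. Both calls were lost with the replicate block (adjusted p = 0.0573 and 0.0877), and Klf6 was also lost with equal array medians (0.0818) and without the eBayes trend (0.0978). Their mean was 0.83 (camera adjusted p = 2.42e-06; adjusted p = 0.559 with an estimated correlation). The list averaged 0.94 on pLV-miR-16 array 1 and 0.13 and 0.18 on arrays 2 and 3. Of these genes 8 rose without pLV-miR-16 array 1, and with the beta-actin covariate the mean was 1.31 (adjusted p = 1.33e-09). Of 36 genes of the unfolded protein and integrated stress response 2 rose and 0 fell, Atf3 and Ddit3 (2.15 ± 0.17, adjusted p = 0.0107), with 8 risen and 2 fallen over the list alone; with the block only Ddit3 passed (adjusted p = 0.0318). The list was not shifted (mean 0.33, camera adjusted p = 0.166), and 12 rose and 3 fell without pLV-miR-16 array 1. None of 33 hypoxia and glycolysis genes passed, with 1 risen over the list alone. Adm, the member with the smallest p, differed by 1.94 ± 0.30 (adjusted p = 0.0577). That list had a mean of 0.38 (camera adjusted p = 0.0023; adjusted p = 0.559 with an estimated correlation). Its call was lost without pLV-GFP array 1 (mean 0.21, adjusted p = 0.0514). The mean was 0.64 without pLV-miR-16 array 1, with 9 risen (adjusted p = 1.43e-06), and 0.25 and 0.24 without pLV-miR-16 array 2 or 3 (adjusted p = 0.0461 and 0.0457). With the beta-actin difference as a covariate, the interferon response (mean 0.00, adjusted p = 0.476), hypoxia (mean -0.09, adjusted p = 0.541), p53 (mean 0.54, adjusted p = 0.0796) and G2/M (mean -0.27, adjusted p = 0.086) lists lost their calls. Apoptosis regulators were not shifted with all arrays (0 of 30 passed, 3 risen and 1 fallen over the list alone, mean 0.15, adjusted p = 0.166), and Birc3 differed by 1.27 ± 0.23 (adjusted p = 0.0879). That list was called without pLV-miR-16 array 1 (mean 0.34, adjusted p = 0.0201), with 8 risen and 1 fallen; without pLV-GFP array 1, 1 fell.

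**Figure D3:**
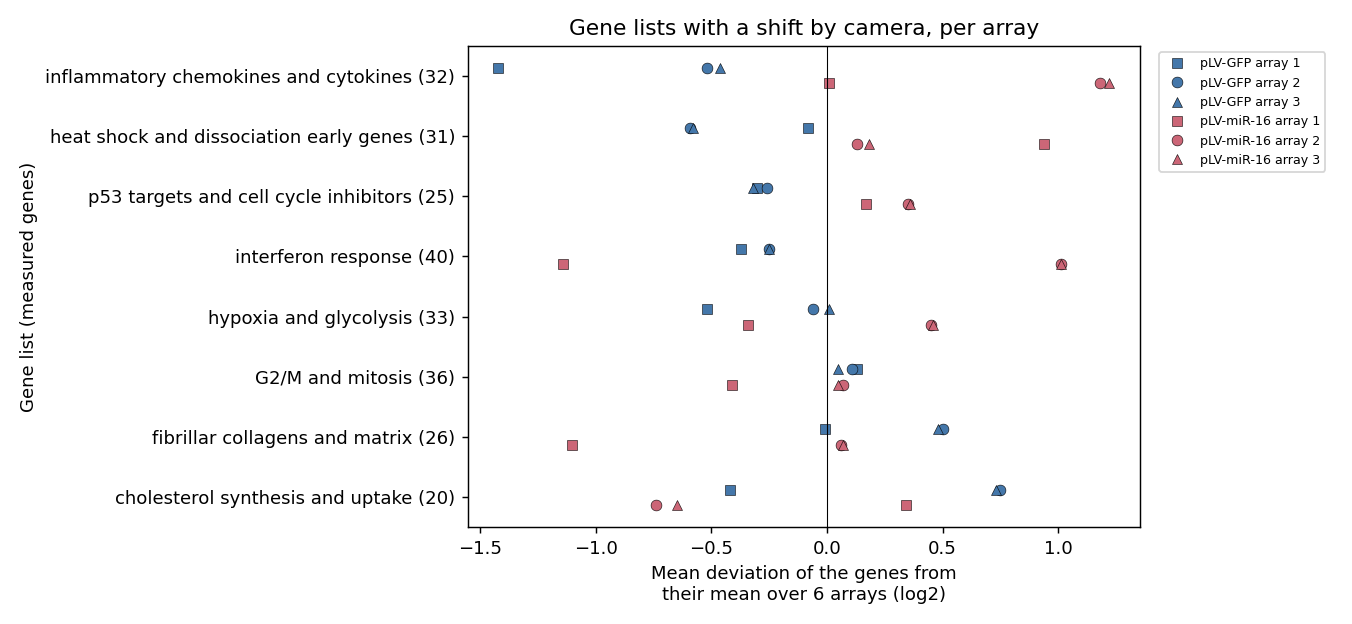
Mean deviation of each list's measured genes from their mean over the 6 arrays, in log2 units, for the 8 lists that camera called, with 1 point per array. The interferon response genes lie at -1.14 on pLV-miR-16 array 1 and at 1.01 on arrays 2 and 3, and the cholesterol genes at -0.42 on pLV-GFP array 1 and at 0.75 and 0.73 on arrays 2 and 3.

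Fibrillar collagens and matrix genes shifted down (mean log2 difference -0.65, camera adjusted p = 0.00079; adjusted p = 0.559 with an estimated correlation). Of 26 measured genes only Col3a1 fell and 0 rose, with 3 fallen over the list alone. Col1a1, the main chain of type I collagen, differed by -1.44 ± 0.29 (adjusted p = 0.124; 0.0284 without pLV-miR-16 array 1). The list averaged -1.10 on array 1 of pLV-miR-16 against 0.06 and 0.07 on arrays 2 and 3. On the pLV-GFP arrays it averaged -0.01, 0.5 and 0.48, so the groups overlapped. Without that array the call was lost (mean -0.26, adjusted p = 0.123), while 7 genes fell and 2 rose. Array weights (adjusted p = 0.0619) and leaving out both arrays numbered 1 (mean -0.42, adjusted p = 0.052) also ended it, and with the beta-actin covariate the mean was -1.20 (adjusted p = 2.69e-05). Basement membrane genes (0 of 16 passed, 2 fallen over the list alone, mean -0.29, adjusted p = 0.124) were not called in the main comparison. Nor were matrix metalloproteinases and inhibitors (0 of 17, 1 risen over the list alone, mean -0.11, adjusted p = 0.547). Contractile and myofibroblast genes (0 of 25, 1 fallen over the list alone, mean -0.14, adjusted p = 0.202) were not called either. Basement membrane genes were called down with no filter on dim probe sets (mean -0.32, adjusted p = 0.0408). They were also called without pLV-miR-16 array 2 (mean -0.40, adjusted p = 0.0461) and with the beta-actin covariate (mean -0.70, adjusted p = 0.00299). Leaving out pLV-miR-16 array 1, 1 basement membrane and 2 contractile genes fell, and 1 metalloproteinase-list gene rose and 1 fell. The members with the smallest p were Col4a5 at -1.46 ± 0.26 (adjusted p = 0.088), Mmp2 at 1.94 ± 0.41 (adjusted p = 0.137) and Tpm1 at -1.04 ± 0.20 (adjusted p = 0.108). The activation marker Acta2 (smooth muscle actin) stood at 7.82 ± 0.61 in pLV-miR-16 and 7.80 ± 0.34 in pLV-GFP (SD, n = 3 each; log2 difference 0.02 ± 0.36). Timp1, an inhibitor of matrix degradation, differed by 0.25 ± 0.30 (adjusted p = 0.796), and Pparg, a regulator of the quiescent state, by -0.03 ± 0.52 (adjusted p = 0.991).

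None of 40 measured genes reported as miR-15/16 targets passed, also over the list alone (mean 0.21, camera adjusted p = 0.202). In the simulation the fit called 0% of 1.5-fold and 4% of 2-fold changes. Falls of that size in single targets would therefore mostly have been missed. Wee1, a mitotic checkpoint kinase, had the smallest p, at -0.83 ± 0.21 (adjusted p = 0.193; 0.0436 without pLV-miR-16 array 1). The cell cycle regulator Ccnd1 (cyclin D1) differed by 0.08 ± 0.88, its pLV-miR-16 arrays reading 7.81, 11.40 and 11.14 against 10.04 ± 0.15 in pLV-GFP, and without pLV-miR-16 array 1 the difference was 1.23 (adjusted p = 0.00702). In all 5 of these genes rose and 1 fell without that array: Wee1 fell, and Ccnd1, Vegfa (1.72), Jun (1.30), Cadm1 (1.14) and Map2k1 (0.56) rose, the last 4 named after their values were seen; the list was not called there (mean 0.18, adjusted p = 0.123). Ccne1 (cyclin E1) differed by 0.04 ± 0.17, the survival factor Bcl2 by -0.11 ± 0.57, the checkpoint kinase Chek1 by -0.31 ± 0.38 and the G protein subunit Gna12 by -0.14 ± 0.24, with the other Gna12 probe set of the opposite sign; all had adjusted p-values of 0.80 or more. Cdk6 was below the filter, at 4.59 ± 0.59 in pLV-miR-16 and 4.99 ± 0.19 in pLV-GFP (SD, n = 3 each). Bcl2 lay just above the filter level of 5.27, at 5.58 ± 0.53 in pLV-miR-16 and 5.69 ± 0.95 in pLV-GFP.

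G2/M and mitosis genes shifted down slightly (mean -0.19, camera adjusted p = 0.0131; adjusted p = 0.559 with an estimated correlation), with 0 of 36 genes passing and 1 fallen over the list alone. Pttg1 differed by -1.04 ± 0.19 (adjusted p = 0.0931). The list averaged -0.41 on pLV-miR-16 array 1 and 0.07 and 0.05 on arrays 2 and 3. On the pLV-GFP arrays it averaged 0.13, 0.11 and 0.05, so the groups overlapped. Without pLV-miR-16 array 1 the mean difference was -0.04 (adjusted p = 0.428), and without pLV-GFP array 1 it was -0.18 (adjusted p = 0.113). G1/S and DNA replication genes were not called in the main comparison (0 of 40 passed, also over the list alone, mean -0.07, adjusted p = 0.124). Mcm2 differed by -0.50 ± 0.16 (adjusted p = 0.288). Camera called the G1/S list down with no filter on dim probe sets (mean -0.08, adjusted p = 0.0408). In the fit without pLV-miR-16 array 1, 1 G2/M gene fell and 2 G1/S genes rose.

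Cholesterol synthesis and uptake genes shifted down (mean -0.71, camera adjusted p = 0.000131; adjusted p = 0.559 with an estimated correlation), with 0 of 20 passing, also over the list alone, and Lss, a sterol-synthesis enzyme, at -1.52 ± 0.45 (adjusted p = 0.262). The groups overlapped: the list averaged -0.42, 0.75 and 0.73 on the pLV-GFP arrays and 0.34, -0.74 and -0.65 on the pLV-miR-16 arrays. The mean was -1.09 without pLV-GFP array 1, with 1 fallen, and -1.05 without pLV-miR-16 array 1, with 5 fallen. It was -1.44 without both, with 20 of 20 fallen, -1.36 with array weights, -1.11 with the beta-actin covariate and -0.34 with arrays 2 and 3 averaged (adjusted p = 0.037). The fit without both called 6538 of all 18625 probe sets. It takes the spread from arrays 2 and 3 alone, which lay close together and may be repeats of the same culture. The 20 of 20 is therefore weak evidence for this list. Adipogenic and fatty acid genes (0 of 25 passed, mean -0.10, adjusted p = 0.36) were not called in the main comparison. Nor were oxidative phosphorylation genes (0 of 38, mean -0.09, adjusted p = 0.0897). With all arrays kept, camera called the latter down with equal array medians (mean -0.21, adjusted p = 0.00835) and array weights (mean -0.17, adjusted p = 0.00203). It also did so after quantile normalisation (adjusted p = 0.023) and with no filter (adjusted p = 0.0338). The members of these lists with the smallest p were Elovl6 at -1.0 ± 0.24 (adjusted p = 0.17) and Ndufb5 at -0.42 ± 0.14 (adjusted p = 0.323). Ribosomal protein genes (0 of 26, mean 0.01, adjusted p = 0.976) were not called in the main comparison. Nor was microRNA and RNA interference machinery (0 of 17, mean -0.12, adjusted p = 0.313). Rpl14 differed by -0.29 ± 0.18 (adjusted p = 0.583) and Ago1 by -0.51 ± 0.20 (adjusted p = 0.395). In these 4 lists none of the genes passed over the list alone. Without pLV-miR-16 array 1, oxidative phosphorylation (mean -0.17, adjusted p = 0.000501) and ribosomal protein genes (mean -0.16, adjusted p = 0.039) were called as shifted down. In that fit 1 oxidative phosphorylation gene fell, and 2 adipogenic genes rose and 4 fell. The ribosomal list was called up with the beta-actin covariate (mean 0.34, adjusted p = 4.03e-05) and down after quantile normalisation (mean -0.09, adjusted p = 0.0136).

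Among signalling lists, 1 of 29 Wnt genes fell, Sfrp4 (adjusted p = 0.118 with the replicate block, 0.0574 with equal array medians and 0.0692 without the eBayes trend), with 3 fallen over the list alone and no shift of the list (mean -0.23, adjusted p = 0.202). TGF-beta and BMP signalling genes (0 of 36, 1 risen and 1 fallen over the list alone, mean -0.08, adjusted p = 0.202) and PDGF, FGF, EGF and VEGF ligands and receptors (0 of 24, 1 risen and 1 fallen over the list alone, adjusted p = 0.976) were not shifted; the mean and median of the latter were 0.06 while camera gave the direction down. Inhba differed by 2.01 ± 0.38 (adjusted p = 0.105) and Igfbp6 by -1.50 ± 0.26 (adjusted p = 0.0843) by their representative probe sets, and for each of them another probe set passed. Of the Wnt genes 7 fell without pLV-miR-16 array 1, where 2 TGF-beta and BMP genes rose and 4 fell and 3 growth factor genes rose and 3 fell. Without pLV-GFP array 1, 1 growth factor gene rose and 1 fell. The Wnt list was called with the filter at the 60th percentile (mean -0.62, adjusted p = 0.0128).

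Markers of liver cell types were read as levels, by the percentile of each gene's mean signal among all genes on the array. Signals of different probe sets do not measure relative abundance, so these percentiles describe brightness only. Quiescent stellate cell markers were mostly dim, with a median percentile of 22.1 over 21 genes; Lrat, the retinol-esterifying enzyme of these cells, stood at 2.85 ± 1.96 in pLV-GFP and 2.48 ± 1.19 in pLV-miR-16 (SD, n = 3 each). Contractile genes (median 70, 12 of 28 above the 75th percentile) and matrix genes (76.9, 17 of 32) were bright as lists. Brightness was uneven within the contractile list: Vim stood at percentile 99.8, but Acta2 at 45.9 and Tagln at 38.6. Vim and Tagln were named after their values were seen. Hepatocyte (16.7), endothelial (14.3), macrophage and Kupffer cell (19.6), lymphocyte (12.7) and cholangiocyte and progenitor markers (25.3) were dim as lists. The portal fibroblast and mesothelial list had a median of 42.5, with Msln, a mesothelial surface protein, at 11.48 ± 0.64 in pLV-GFP and 11.15 ± 0.96 in pLV-miR-16 and Wt1, a mesothelial transcription factor, at 11.61 ± 0.37 and 10.17 ± 0.69.

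The portal fibroblast, cholangiocyte, quiescent stellate and macrophage lists were not called in the main comparison. The portal fibroblast and mesothelial list had 1 of 17 genes fallen, Krt8 (adjusted p = 0.137 with the replicate block, 0.0898 with equal array medians and 0.0882 without the eBayes trend), with 4 fallen over the list alone and a mean of -0.48 (adjusted p = 0.124). It was called as shifted down under 5 alternatives, with means from -0.88 to -0.45 and adjusted p-values from 0.0162 to 0.0408. The cholangiocyte and progenitor list had 2 of 8 fallen, Tspan8 and Krt8, with 2 fallen over the list alone as well. Neither Tspan8 nor Krt8 passed with the block or without the trend. This list had a mean of -0.63 against a median of 0.11 (adjusted p = 0.432). Quiescent stellate cell markers (0 of 9, also over the list alone, mean 0.00, adjusted p = 0.976; Pdgfra at -0.88 ± 0.69, adjusted p = 0.671) and macrophage and Kupffer cell markers (0 of 7, 1 risen over the list alone, mean 0.53, adjusted p = 0.36; Cybb at 2.81 ± 0.54, adjusted p = 0.105) did not pass. In the portal fibroblast list 1 gene rose and 4 fell without pLV-miR-16 array 1, and in the macrophage list 1 rose and 1 fell. No gene of the portal fibroblast or cholangiocyte list passed without pLV-GFP array 1 or without pLV-miR-16 array 2. Hepatocyte, endothelial and lymphocyte markers had 3, 4 and 2 measured genes and were not tested as lists; Hpx differed by 1.54 ± 0.81 (adjusted p = 0.526), Esam by -1.43 ± 0.88 (adjusted p = 0.583) and Cd7 by 1.37 ± 1.17 (adjusted p = 0.695).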

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

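The tests of why pLV-miR-16 array 1 stands apart were chosen after the result was seen, as was the count of splits for all changed probe sets; the counts of splits for 2-fold changes and gene lists were set before. The value of the 5S rRNA control was noticed among the 57 control probe sets, which were left out of the tested ones.

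A control probe set for 5S ribosomal RNA was higher in pLV-miR-16, 12.56 ± 1.04 against 9.44 ± 1.29 in pLV-GFP (log2, SD, n = 3 each), a difference of 3.12. All 3 pLV-miR-16 arrays lay above all 3 pLV-GFP arrays, with 11.36, 13.22 and 13.10 against 10.92, 8.58 and 8.81.

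Array 1 of pLV-miR-16 correlated with the other 5 arrays at 0.855 to 0.874. Degraded RNA on that array is argued against by the 5' to 3' difference of beta-actin, -3.16 there and lower, -3.88, on another array. A minority of other cells mixed in can lower a gene by less than 2-fold, whereas 125 genes at 7 or more on each other array were at least 4-fold lower on this array, against at most 10 for any other array; this criterion replaced a first one, genes at 8 or more and at least 16-fold lower, which gave 3 against at most 1 and decided nothing, so its weight is limited. A hybridisation or scan batch shared by the arrays numbered 1 stays open: pLV-GFP array 1 had a mean r with its own group that was higher by 0.085, but those correlations define the pattern and a batch need not act alike on both arrays, which had the brightest hybridisation controls (11.78 and 12.24 against 11.23 to 11.40); a first rule, changed after its result was seen, had excluded the batch on the 0.085 alone. A different culture or a wrong sample label also stays open, and besides a loss of chromosome segments no biological explanation was tested.

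The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 92 changed probe sets and 90 changed at least 2-fold. The highest of the other splits gave 0 for each, so 1 of 10 splits gave as many. At an unadjusted p under 0.05 in limma's test the real split gave 2146 probe sets and the others 32 to 1604. The 1604 came from pLV-GFP array 1 with pLV-miR-16 arrays 2 and 3 against the rest. Every other split also mixes the infections within a side, so a group difference would widen its spread and lower its count. For gene lists the real split gave 8, and pLV-GFP arrays 1 and 3 with pLV-miR-16 array 1 against the rest gave 10, so 2 of 10 splits gave as many; the other splits gave 5 to 7, which shows that list calls at a preset correlation also arise from the structure among these arrays. The 3 other splits that part all 3 same-numbered pairs gave 0 changed probe sets each.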

How the results depend on the processing

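Of the alternatives, 4 were chosen after seeing the data: the arrays numbered 1 as a batch, both arrays numbered 1 left out, arrays 2 and 3 averaged into 1 replicate, and the beta-actin covariate. The seed-site test and its alternatives were not run. Signal over background limits dim genes, as the values carry no detection calls.

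The count of 92 changed probe sets stayed between 66 and 111 under both pseudocounts, quantile normalisation, both filters, robust eBayes and 1 probe set per gene. It was 59 with equal array medians, 32 without the trend, 8096 with array weights, 15 with the replicate block, 418 with the batch, 6538 without both arrays numbered 1, 0 with arrays 2 and 3 averaged and 26 with the beta-actin covariate, and 0 to 1358 with single arrays left out. The 90 changed at least 2-fold became 59, 32, 1647, 15, 328, 1495, 0 and 26 in the same settings, and 0 to 767 with single arrays left out. Beside the counts of 0 from limma, 655 probe sets had an unadjusted p under 0.05 with arrays 2 and 3 averaged. The cause was not tested, except that averaging and leaving arrays out use fewer samples and the block and covariate fits estimate more terms. The count was 1358 without pLV-miR-16 array 1 and 73 without pLV-GFP array 1. It was 0 or 4 wherever an array numbered 2 or 3 was left out, and 6538 where only those were kept. The counts thus depended on how far the closely alike arrays 2 and 3 set the spread.

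The 8 shifted lists became 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 1 with fry (8 unadjusted), and stayed between 6 and 12 otherwise. The replicate block ended the call of 53 of the 62 called genes and of 0 lists. With the beta-actin covariate the interferon mean was 0.00 (adjusted p = 0.476), the hypoxia mean -0.09 (0.541), and the G2/M (0.086) and p53 (0.0796) lists lost their calls. That covariate goes partly with the groups, so these losses do not tell RNA integrity from a difference between the groups. Array weights ended the matrix (0.0619) and G2/M (0.609) calls. Lists not called in the main comparison gained 20 calls over these settings, in 7 lists, 6 of them for oxidative phosphorylation (mean -0.21 to -0.09).

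Among named genes, signs turned only where the main difference had not passed. With the beta-actin covariate Rpl14 was 0.01, Hpx -0.10, Ccnd1 -0.91, Ccne1 -0.04, Bcl2 1.00 and Pparg 0.33. With equal medians Ccnd1 was -0.04, Ccne1 -0.08 and Acta2 -0.10. Without both arrays numbered 1 Cd7 was -0.43, Bcl2 0.10, Chek1 0.12 and Acta2 -0.11. With array weights Cd7 was -0.35 and Chek1 0.08. With arrays 2 and 3 averaged Ccnd1 was -0.46, Gna12 0.02 and Pparg 0.30. With pseudocounts of 16 and 64 Pparg was 0.01 and 0.04. With single arrays left out Cd7 ran from -0.10 to 2.20, Ccnd1 from -0.56 to 1.23, Ccne1 from -0.04 to 0.11, Bcl2 from -0.55 to 0.40, Gna12 from -0.37 to 0.02, Chek1 from -0.54 to 0.15, Acta2 from -0.31 to 0.29, Timp1 from -0.08 to 0.43, Pparg from -0.63 to 0.28 and Smc4 from -0.33 to 0.79. The cause was not tested.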

Other observations

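The chromosome-segment and mesothelial tests were set before their results were seen, but the reading of the mesothelial test was changed afterwards; the genes below were picked from the values themselves.

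On pLV-miR-16 array 1 alone, 100 genes at a log2 signal of 8 or more were at least 4-fold above every other array, against at most 1 for any other array. They included the neuroendocrine peptide genes Vgf, at 12.36 where the nearest other array read 6.11, and Nts, at 11.01 against 4.96, the xenobiotic-metabolising Cyp1a1 at 9.48 against 2.82, the cyclin Ccnd2 at 10.56 against 5.03 and the natriuretic peptide gene Nppb at 12.38 against 8.51. In the other direction the same array read 2.15 for Poglut3, against 9.54 on the nearest other array, 6.53 for the collagen receptor Ddr2, against 9.93, and 7.69 for the matrix protease Mmp14, against 11.03. Interferon-inducible genes were also among the low ones, Gbp7 at 7.67 against 10.81 and Ube2l6 at 8.92 against 12.02.

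Of the 1358 probe sets called without pLV-miR-16 array 1, that array lay on the same side of the pLV-GFP mean for 851 (62.7%) and differed by at least 1 log2 the other way for 158. The 1358 were chosen by their difference from the same pLV-GFP arrays and include the 92 called with that array. Both can raise the share, so it is no independent check.

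A loss of whole chromosome segments in the cells of that sample would place the lost genes next to each other. Among 8042 genes at 7 or more on the other arrays, the 125 at least 4-fold lower on it formed 3 neighbouring pairs, against a median of 2 in 10000 permutations (one-sided permutation p = 0.307), which argues against such losses as the source of most of them; the pairs were Parp9 with Dtx3l, Dtx3l with Parp14, and Casd1 with Pon2.

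The mesothelial markers Msln, Wt1 and Krt8 were bright, but Upk1b (percentile 30.9) and Gpm6a (43.1) less so; the stellate cell markers Lrat, Reln and Hgf were dim, but Lhx2 (70.7), Ecm1 (68) and Nes (52.4) less so. Cells with a mesothelial profile in the cultures were considered as a hypothesis. A second list of 10 mesothelial markers, of which Bnc1 was also in the fixed list and Lrrn4 had been seen among the called genes, had a median percentile of 40, above the 22.1 of the 21 stellate cell markers (one-sided permutation test, p = 0.0303). Its brightest genes were Ezr (percentile 95.5), Pdpn (86.3) and Lrrn4 (74.8), and the mesothelial gene Calb2 lay at 7.9. A median above 75 had been set as needed for the hypothesis and one of 50 or less as excluding it. By that bound the 40 excluded the hypothesis. Signals of different probe sets do not measure abundance, however, so such a bound cannot decide it. The quiescent stellate cell list lay lower still (22.1), while the contractile (70) and matrix (76.9) lists lay higher. The test therefore decides nothing and the hypothesis stays open.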
